A study of Acropora aff. hyacinthus sp. E JTL-2012 with 12 samples.

How the data were processed

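RNA was measured in 12 libraries from 6 colonies of the tabletop coral Acropora aff. hyacinthus, each with a fragment in each of 2 back-reef pools, called pool 300 and pool 400. Corals 2, 7 and 75 came from pool 300, and corals 40, 68 and 70 from pool 400. Per the labels, the libraries were made with a TruSeq kit and sequenced 12 to a lane. BWA and DESeq are named in the submitters' processing notes, with versions not given in the sources used here, and neither note says what each did.

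The deposited values are one table of 16980 contigs of an assembled transcriptome by 12 libraries, with a description for each contig. The unit is a signal: read counts divided by a size factor, as the deposited values themselves show, since all values but 1 are whole multiples of what 1 read is worth in their library, between 0.586 and 1.66. The table is headed as raw data and marks the pool 400 columns as adjusted, per the file headers, and what that adjustment was is not given in the sources used here. At a tolerance of 0.01 all values came out whole in 11 libraries, and 1 value did not in the pool 400 library of coral 2, which was read as 0. The recovered totals ran from 557339 to 1643526 reads, with a median of 885480. In pool 300 the deposited factors matched median-ratio factors computed from the recovered reads, with ratios of 1.000 to 1.007. In pool 400 the ratios ran from 0.781 to 1.57. Columns of group means and SDs in the table were not used here. No genome was used here, so contigs have no position, and several contigs can carry one description without being one gene.

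Contigs with a mean of at least 10 over the 12 libraries were tested, 11903 in all. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjusted p under 0.05, so folds are on the log2(value + 1) scale and understate the change of low contigs. Pool effects were fitted with the coral as a block, since both fragments came from one animal, and are pool 300 minus pool 400. Origin was tested on the means of each coral, 3 corals against 3, and is origin 300 minus origin 400. As an alternative, edgeR 4.0.16 (quasi-likelihood) was run on the recovered reads. Other alternatives were other pseudocounts, other minimum means, median-ratio rescaling, quantile normalization, a robust variance, models without the block or with it as a random effect, and each coral left out with both fragments. All of these were chosen before the data were examined. A block with the pool 400 fragments of corals 40 and 68 exchanged, the omission of both corals, and rescaled list tests were added after seeing the data. A change of scaling moves the median of all contigs: it was 0.126 for the pool effect in corals from pool 300, 0.203 for the difference between origins and -0.103 for origin on the deposited scale, and -0.019, -0.0615 and 0.0349 after rescaling.

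Contigs were named by a rule fixed beforehand: for each main comparison, up to 12 of the largest falls and rises past the threshold that moved alike in all corals, the 10 of smallest p where fewer than 10 passed, leaving out contigs without an informative description, and the up to 4 members of smallest p in each gene list. Gene lists were word patterns fixed beforehand and tested with camera (preset correlation 0.01, and estimated) where at least 5 members were measured. An acronym in each of 2 patterns matched inside unrelated words. Both were corrected, and the full name small cysteine-rich protein added to one, after the matches and the first test results had been seen. The ribosomal list matched mitochondrial as well as cytosolic proteins. The lists of Symbiodinium photosynthesis, with 2 measured members, and bacteria, with 1, were too small to test.

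The fits were tested on simulated data in which 200 of 11903 contigs were changed. For the pool effect over 6 corals, 66% of contigs changed 2-fold and 94% of those changed 4-fold were recovered, and 11 of 191 calls were false. For corals from pool 300 alone these were 20% and 66%, with 14 of 150 calls false. For origin they were 0% and 20%, and 86% of contigs changed 16-fold, with 2 of 83 calls false. These rates describe the simulated data and need not carry over to the measured libraries, whose scaling is in doubt. With the signs of some corals reversed, the measured pool effect over 6 corals gave at most 1 contig in the main setting. After median-ratio rescaling such a reversal gave up to 18, and up to 1557 with the exchanged block as well.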

Results

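Fragments of 6 corals were moved on August 3, 2010 and sampled on August 30, 2011, close to noon, so that each coral was measured in both pools. The groups were origin 300 living in pool 300, origin 300 in pool 400, origin 400 in pool 300 and origin 400 in pool 400, with 3 corals in each. Recovered reads per library ran from 557339 in the pool 400 fragment of coral 2 to 1643526 in the pool 400 fragment of coral 70, so contigs with low values rest on few reads. Counting error is the only error that the depth describes.

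The pools differ in how far their water temperature swings, pool 300 being known as the more variable, and the first comparison asked which transcripts depended on the pool a fragment lived in. The contigs that passed were all lower in pool 300 than in pool 400. Protein fosB (contig182044), a subunit of the AP-1 transcription factor, averaged 32.8 ± 21.4 in pool 300 and 199.6 ± 98.5 in pool 400 (SD, n = 6), and fell by 2.85 on the log2 scale (SE 0.41, limma adjusted p = 0.0205). TNF receptor-associated factor 3 (contig180146), an adaptor of immune signalling, fell by 3.28 (SE 0.56, limma adjusted p = 0.0458), with single corals between -5.38 and -0.07. Heat shock protein 83 (contig215125), a chaperone of the Hsp90 family, fell by 2.14, and the small heat shock protein Hsp-16.1/Hsp-16.11 (contig165011) fell by 1.84. These 4 contigs lost their call in other settings: with median-ratio rescaling their limma adjusted p were 0.0754, 0.112, 0.0849 and 0.0904, and with edgeR 0.063, 0.123, 0.063 and 0.063.

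Over all 6 corals 41 of 11903 contigs passed the test, of which 41 were lower in pool 300 and 0 higher. The named contigs also included Synaptotagmin-15 (contig120807), at a log2 difference of -2.91, Ras-related protein Rab-30 (contig130463), a regulator of vesicle traffic, at -2.82, and Balbiani ring protein 3 (contig121470) at -2.66. In pool 300 Synaptotagmin-15 was at the worth of 1 read in corals 2 and 7, and Heat shock protein 83 in coral 2. Serine/threonine-protein kinase SIK2 (contig149663) was at -2.58 and Rab11 family-interacting protein 3 (contig188763) at -2.38. Juxtaposed with another zinc finger protein 1 (contig79841) was at -2.05, Claspin (contig107904), a protein of the DNA replication checkpoint, at -1.93, and Probable N-acetyltransferase CML1 (contig97762) at -1.81. The naming rule required a fall in all 6 corals, which holds on the deposited scale. After median-ratio rescaling 25 of the 41 contigs were lower in all 6 corals and 16 were higher in pool 300 in coral 70, among them TNF receptor-associated factor 3 (0.57), Rab-30 (0.10) and Rab11 family-interacting protein 3 (0.27), while all 41 were lower in the other 5 corals. The median difference of coral 70 over the 41 went from -0.75 to -0.13, and that over all contigs from -0.53 to 0.097, so rescaling shifted all contigs of that coral. The count depended on the scaling: with median-ratio rescaling 8 contigs passed, and edgeR on the recovered reads called the same 8. They were Balbiani ring protein 3, Juxtaposed with another zinc finger protein 1, CML1, GFP-like fluorescent chromoprotein FP506 (contig152508) and 4 chosen after their values were seen, Steroid 17-alpha-hydroxylase/17,20 lyase (contig145436), Transcriptional regulator ERG (contig175601) and a pair without an informative description (contig80872 and contig81868). With rescaling, another sign pattern of the corals, with coral 70 reversed, gave 18 contigs. Leaving out coral 2, 7, 75 or 40 left between 4 and 5 of the 41 contigs. Leaving out coral 68 gave 28, of which 23 were among the 41, and leaving out coral 70 gave 74, of which 38 were.

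**Figure D1:**
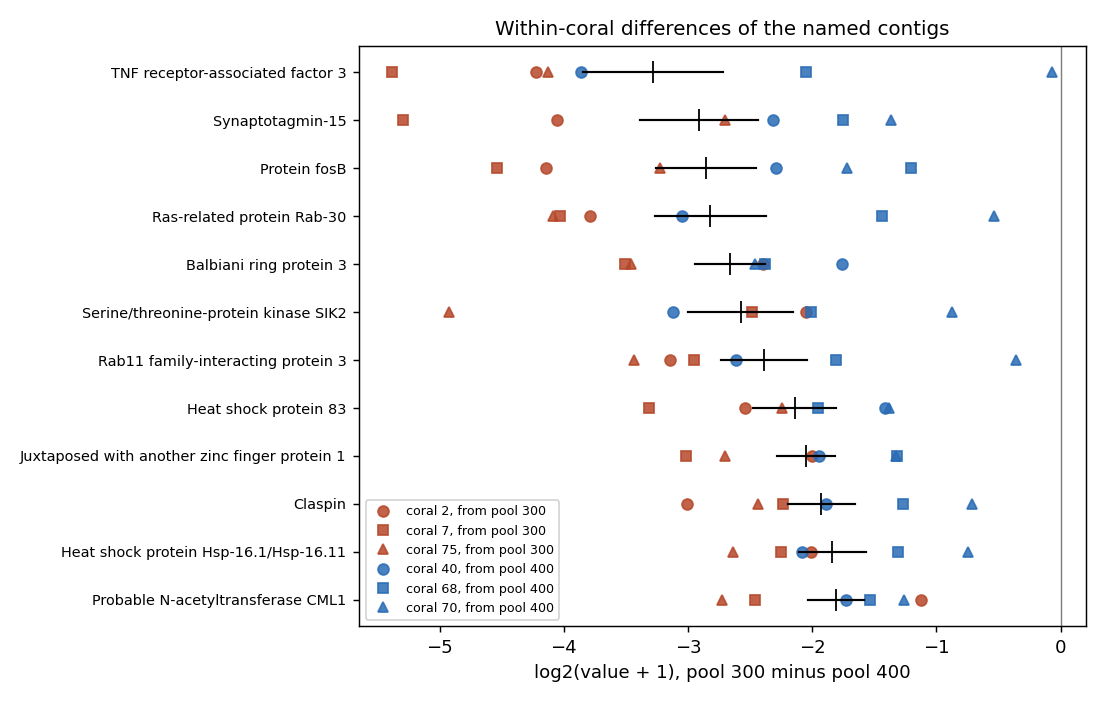
Difference in log2(value + 1) between the fragment in pool 300 and that in pool 400 of each coral, for the 12 named contigs. Points are corals, coloured by pool of origin, and the black tick and bar are the limma estimate and its SE. On the deposited scale all points lie below 0, as the naming rule required, and after median-ratio rescaling 3 of the 12 contigs lie above 0 in coral 70.

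Of 87 measured heat shock proteins and chaperones, 2 fell over all contigs tested and 11 adjusted over the list alone. Heat shock factor protein 1 (contig145533), the regulator of heat shock genes, had a log2 difference of -1.26 (limma adjusted p = 0.0525) and Heat shock protein 68 (contig187488) one of -2.50 (limma adjusted p = 0.0538). The list ranked low among all contigs by camera (adjusted p = 0.000813), with adjusted p = 0.946 with an estimated correlation. Its median log2 difference was -0.058 where all contigs had 0.03, and 58.6% of its members were lower in pool 300. In corals from pool 300 the share was 35.6%, and in corals from pool 400 it was 73.6%. The rank thus does not mean that the whole list fell. Among 10 fluorescent proteins and chromoproteins, GFP-like fluorescent chromoprotein FP506 (contig152508) fell by 1.66 (limma adjusted p = 0.00703), 2 fell adjusted over the list alone, and camera gave adjusted p = 0.0184, with adjusted p = 0.946 with an estimated correlation. Of 21 muscle proteins, 0 passed over all contigs and 1 rose adjusted over the list alone. Tropomyosin-2 (contig112464) had a log2 difference of 0.80 (limma adjusted p = 0.143). The muscle list ranked high by camera (adjusted p = 0.0184), and again had adjusted p = 0.946 with an estimated correlation. The fluorescent list lost its call with rescaling (camera adjusted p = 0.0769) and with the fragments of corals 40 and 68 exchanged (camera adjusted p = 0.49). At the preset correlation the heat shock and muscle lists kept theirs in both settings. As many as 3 lists were called in 7 of the 32 sign patterns of the corals.

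In the remaining lists few or no members passed over all contigs. TNF receptor-associated factor 3 was the member called among 86 of the TNF receptor, TRAF and apoptosis list, where 3 fell adjusted over the list alone, and Interferon regulatory factor 2-binding protein 1 (contig155851) fell by 1.57 among 96 of innate immunity and lectins. Carbonic anhydrase (contig181281), of 31 calcification members, had a log2 difference of -0.72 (limma adjusted p = 0.121). Markers of cnidocytes (6 members), oocytes and germ line (23), and sperm and cilia (75) had 0 calls each, and their medians lay -0.10, -0.08 and -0.02 from that of all contigs. The lists of antioxidants (83), oxidative phosphorylation (71), circadian clock (10) and ubiquitin and proteasome (268) also had 0 calls over all contigs. Of Symbiodinium, the algae living in the coral, Photosystem II CP47 chlorophyll apoprotein (contig194637) had a log2 difference of -0.35 between pools and 3.38 between origins (limma adjusted p = 1 and 0.998). The bacterial list's member (contig174661) had -0.11 between pools (limma adjusted p = 1).

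The second comparison asked whether corals of both origins responded alike. In corals from pool 300 alone, 64 contigs were lower in pool 300 and 2 were higher. With rescaling 48 were lower and 0 higher, and with edgeR 43 and 0. Leaving out coral 2 gave 9 calls, coral 7 gave 29 and coral 75 gave 54. In the same corals the median of the cnidocyte markers lay -0.554 from that of all contigs (SE 0.255, 6 members) and that of the muscle proteins 0.296 (SE 0.107, 21 members). These SEs are over list members and do not measure the spread between corals. Over all 6 corals the list medians of single corals ran from -0.846 to 0.884 for cnidocytes and from -0.529 to 0.725 for muscle. The BAG domain-containing protein Samui (contig600116), named for a domain of Hsp70 co-chaperones, fell by 4.84, and DnaJ protein homolog 1 (contig169202), a co-chaperone, fell by 3.42. Myc proto-oncogene protein (contig139133) fell by 2.28. In corals from pool 400 limma and edgeR called 0 contigs, with 244 and 324 at an unadjusted p under 0.05. Both lie under the 595 of 11903 that chance alone would give. Limma gave 580 such contigs over all 6 corals and 561 in corals from pool 300, also under 595. There edgeR gave 655 and 540. A low count is thus not particular to comparisons without calls. Of the 64 contigs, 62 were also lower in pool 300 in corals from pool 400 on the deposited scale. Their median log2 difference there was -0.98, as low in 1 of the 8 sign patterns of those corals (share 0.125). The median of all contigs in those corals was -0.0868, and 0.0368 after rescaling. In coral 70 alone that median was -0.53, and 0.097 after rescaling. The difference between origins itself was tested, and limma called 0 contigs, where edgeR called 1. By limma 211 had an unadjusted p under 0.05, again fewer than the 595 that chance would give.

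The contigs of smallest p for that difference did not pass. A contig described as C2 domain-containing protein C31G5.15 (contig182707) was 1.65 lower in pool 300 in corals from pool 300 and 1.84 higher in corals from pool 400 on the log2 scale (limma adjusted p = 0.0771), and passed with edgeR (adjusted p = 0.00624) and with rescaling (limma adjusted p = 0.00643). With the pool 400 fragments of corals 40 and 68 exchanged it passed with neither (adjusted p = 1 and 0.98). Protein fosB (contig182044) had effects of -3.97 and -1.74, and Transcription factor AP-1 (contig211469) -2.55 and -0.96, with a limma adjusted p of 1 for each difference. The 68 ribosomal proteins ranked low by camera (adjusted p = 0.00994), with a median of -0.07 where all contigs had 0.203, and adjusted p = 0.615 with an estimated correlation. Across contigs the pool effects of both origins had Pearson r = 0.22 and Spearman rho = 0.0679 (exact one-sided sign-flip permutation p = 0.156). Contigs are not independent replicates.

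The third comparison asked what stayed with a coral's pool of origin. Tumor necrosis factor receptor superfamily member 16 (contig176696), a receptor of the TNF family, averaged 238 ± 39.3 in corals from pool 300 and 27.0 ± 7.84 in corals from pool 400 (SD, n = 3 corals), a log2 difference of 3.22 (SE 0.29, limma adjusted p = 0.00274). C-type lectin domain family 10 member A (contig71140), a carbohydrate-binding protein, was at 6.59 ± 5.16 in corals from pool 300 and 335 ± 75.8 in corals from pool 400 (SD, n = 3; limma adjusted p = 0.00274). Fibrillin-1 (contig218313), an extracellular matrix protein, was at 1.04 ± 0.90 and 76.5 ± 22.7 (SD, n = 3; limma adjusted p = 0.00873), the former under the worth of 3 reads in any library. A contig without an informative description (contig58852), chosen after its values were seen, was the remaining one of 4 called. Fibrillin-1 and contig58852 each had no read in either fragment of 1 coral, where an allele too different to align would also read as absent. With rescaling 1 was called, the TNF receptor contig, and edgeR called 3, of which 2 were among the 4.

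**Figure D2:**
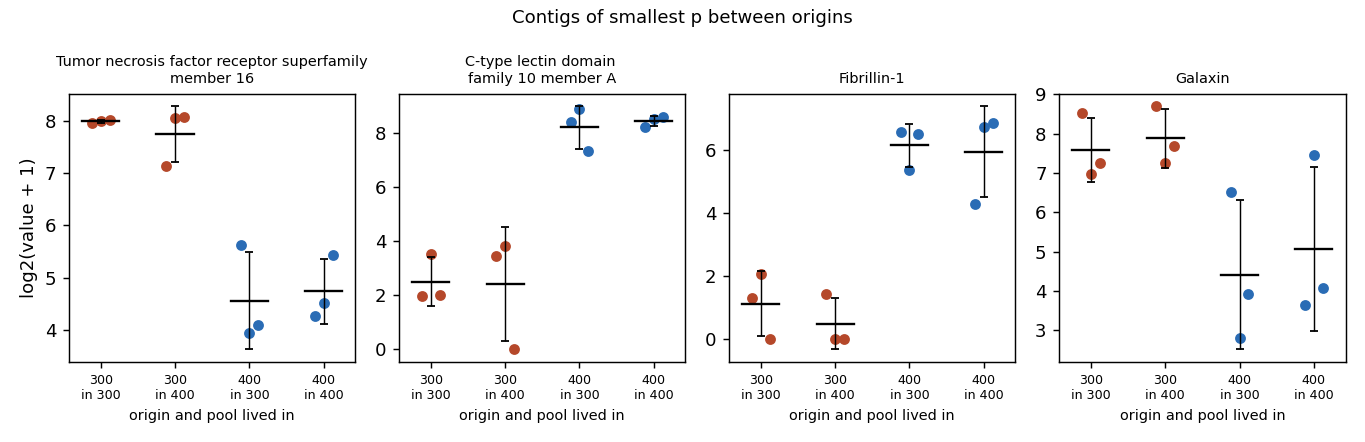
Values as log2(value + 1) of the 4 named contigs of smallest p between origins, by pool of origin and pool lived in. Points are corals, lines are means and bars SDs (n = 3 per group). C-type lectin domain family 10 member A and Fibrillin-1 are lower and the TNF receptor contig and Galaxin higher in corals from pool 300, in both pools.

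Other contigs of small p did not pass. Galaxin (contig184232), a protein of the coral skeleton's organic matrix, had a log2 difference of 3.00 (limma adjusted p = 0.0555), and 2 of 31 calcification members were higher adjusted over the list alone. Another contig of Tumor necrosis factor receptor superfamily member 16 (contig177460) had a difference of 1.82 (limma adjusted p = 0.533), and a further one (contig179731) had -0.93 (limma adjusted p = 0.998). Of the 10 measured contigs of that description 1 passed. Major vault protein (contig219416) had a log2 difference of -3.38, and Rootletin (contig209488) averaged 29.2 ± 11.6 in corals from pool 300 and 1.53 ± 2.65 in corals from pool 400 (SD, n = 3; limma adjusted p = 0.533 for each). The 68 ribosomal proteins ranked high (camera adjusted p = 0.00792, with adjusted p = 0.984 with an estimated correlation) and had 0 members passing. Within pool 300, limma called 1 contig between origins and within pool 400 it called 3, where edgeR called 0 in each. Within pool 400, leaving out coral 75 gave 91 and leaving out coral 40 or 70 gave 0.

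Of the total spread of log2 values, origin took 12.7% (exact permutation p = 0.5, smallest possible 0.1), coral within origin 51.2%, pool 6.03% (exact permutation p = 0.469), the difference between origins in pool effect 4.66% and the residual 25.4%. The shares are sums of squares that were not divided by their degrees of freedom. Coral within origin and the residual have more of these than origin or pool, so the sizes of the shares cannot be compared directly. Origin and pool effects had Pearson r = -0.0109 across contigs (exact two-sided sign-flip permutation p = 0.938).

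**Figure D3:**
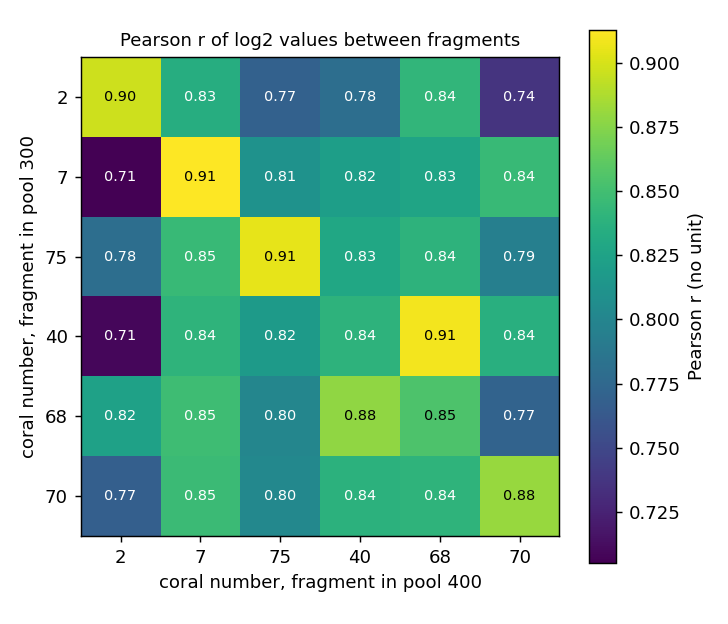
Pearson r of log2 values, rescaled by median ratios, between each fragment in pool 300 and each in pool 400. Corals 2, 7, 75 and 70 have their highest r with their own number, while the pool 300 fragments of corals 40 and 68 have theirs with the other number, at 0.909 and 0.878.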

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

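The tests of exchanged labels, of one genotype, of scaling, of cell types, of the sampling day and of the size of response were chosen after the results were seen. So were the sign patterns in settings other than the main one. The tests of depth, of coral 2 and of other groupings in the main setting were set before their results.

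The fragments of corals 40 and 68 paired across their numbers. Contigs without a read in one fragment and at 20 or more in the other numbered 84 in the pairs as labelled and 26 in the crossed pairs. Fewer in the crossed pairs is what exchanged labels in one of the pools would give, but these data cannot place the pool. The match was not clean: the crossed pairs had 14 and 12 such contigs. The own pairs of corals 2, 7, 75 and 70 had 11, 1, 5 and 2. One genotype behind both corals is argued against, since their highest r within a pool was 0.8231 and the lowest between fragments of one other coral 0.880. Depth stays open: thinned to 557339 reads, the crossed r exceeded the labelled one by at least 0.0137, short of the 0.02 set beforehand, because the pool 300 fragment of coral 68 had r = 0.868 and 0.854. Both corals came from pool 400, so an exchange leaves the groups as they are.

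For the contigs lower in pool 300, sign patterns were run in 7 settings. In 3 of them no other pattern reached the real count, a share of 0.0312, the smallest that 32 patterns allow. Those shares were not adjusted for the 7 settings, which disagree, so chance is not excluded. On the deposited scale with corals paired as labelled, 1 of 32 sign patterns gave 41 contigs and the highest other gave 1. With edgeR these were 8 and 1, and with the crossed block 63 and 24. With rescaling other patterns gave as many, at 8 contigs and 18 in another pattern. So they did for the crossed block with rescaling, at 1 and 1557, and with edgeR, at 13 and 1494. Without corals 40 and 68 all 8 patterns gave 0. The median log2 difference of the 41 was -1.57 (median SE 0.207), and -1.59 (0.263) after rescaling. A library's factor moves all contigs alike, and the median of all contigs was 0.0297, so the 41 lay -1.6 from it, before and after rescaling. The 41 were picked from these data for their falls, so this distance was bound to be large. It cannot decide whether scaling was a source of the average fall. Rescaling itself also says little of that, since it moved the median contig by -0.0123. The calls that ended under rescaling did so at a larger SE. In coral 70 the falls do depend on scaling, with a median of -0.75 before and -0.13 after. This is a shift of the whole library, since the median of all contigs in coral 70 went from -0.53 to 0.097. Without coral 2, whose pool 400 library was the shallowest, the median was -1.54. The 41 were picked with coral 2 in the fit and fell in the other corals too. This median was therefore bound to stay low and cannot decide on that library. A different mix of cell types stays open: of 4 marker lists, muscle lay farthest from all contigs, at 0.141 (SE over members 0.0793), where 0.145 is the bound set for it. Each pool was sampled on 1 day, so a lasting pool effect and the conditions of that noon cannot be told apart.

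Corals from pool 300 had 66 calls and corals from pool 400 had 0. With crossed numbers corals from pool 400 still had 0. Crossing leaves the mean pool effect of these corals as it is and changes only its error, so this is a weak test of exchanged labels. After rescaling there were 48 and 0, but 41 of the 48 were among the 66, short of the bound of 44 kept calls set for scaling, so scaling stays open. A larger response of corals from pool 300 may be the reason, but 2 of the 10 splits of the corals gave as large a difference of medians, the real one 0.649 and the highest other 0.696, and 10 splits are too few to decide. A different mix of cell types stays open too, since the cnidocyte markers lay -0.554 (SE over members 0.255) from all contigs in corals from pool 300, against a smallest fall of 0.728. How many of the 64 contigs had p under 0.05 in corals from pool 400 hung on the variance estimate: 4 estimates were tried and gave 56, 35, 17 and 1, and nothing here rests on that number.

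Total reads stood apart in the pool 400 library of coral 70, at 1643526 against 557339 to 917838 in the others (gap over range 0.668). It was the 1 of 20 groups of 6 with such a gap, where chance gives about 1. The ribosomal list differed between origins in its pool effect (camera adjusted p = 0.00994, and adjusted p = 0.615 with an estimated correlation), and 8 of the 10 splits gave as many as 1 list, the highest other 3.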

How the results depend on the processing

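The crossed block, the omission of corals 40 and 68, the rescaled list tests and the first list patterns were chosen after seeing the data. Depth limits the low contigs, and causes below were not tested unless given. Over all corals, 41 contigs became 8 with median-ratio rescaling, 18 with quantile normalization, 80 with the replicate block as a random effect, 8 with edgeR, 63 with the crossed replicate block, 1 with it and rescaling, 13 with it and edgeR, and 0 without corals 40 and 68, where fewer corals were tested. The 8 kept under rescaling and under edgeR were all among the 41. In corals from pool 300, 66 became 42 with no replicate block and 43 with edgeR. The difference between origins went from 0 to 2 with rescaling, 2 with quantile normalization and 1 with edgeR, and was 0 with the crossed block, also together with rescaling or edgeR. Origin went from 4 to 1 with rescaling, 0 with quantile normalization and 8 with no replicate block. The last counts both fragments of a coral as separate replicates of origin, which they are not. Origin calls were 1 with the crossed block and rescaling, 0 with the crossed block and edgeR, and 0 without corals 40 and 68. Origin within pool 400 went from 3 to 6 with a pseudocount of 5, 5 with no filter and 0 with edgeR, and within pool 300 from 1 to 0 with edgeR. Lists went from 3, 1 and 1 (pool, difference, origin) to 0, 0 and 0 with an estimated correlation. For the difference they were 2 with rescaling and 3 without corals 40 and 68, and for origin 2 with the crossed block. The share of pool was 8.95% at a mean of at least 50 and 7.74% with quantile normalization.

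Leaving out each coral, contigs called ran from 4 to 74 over all corals, 9 to 94 in corals from pool 300, 0 to 0 in corals from pool 400, 0 to 2 for the difference, 2 to 12 for origin, 0 to 5 within pool 300 and 0 to 91 within pool 400. Correlations ran from -0.0187 to 0.443 between origins and -0.101 to 0.0734 between origin and pool effects. Shares ran from 13.1% to 18.6% for origin, 43.1% to 52.0% for coral, 5.85% to 8.95% for pool, 3.84% to 8.83% for the difference and 18.5% to 30.9% for the residual. Lists ran from 0 to 6, 0 to 2 and 0 to 4. The named contigs of the pool comparison kept their call in 127 of the combinations of contig and setting and lost it in 109, with no reversal.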

Other observations

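Some transcripts were present or absent by coral. In 66 contigs, 1 coral or more had no read in either fragment while another had 20 or more in both, and 28 of these carried an informative description. With the fragments of corals 40 and 68 crossed there were 97, of which 37 did. The values below are for the pairs as labelled. Fluorescent proteins and chromoproteins held 3 of them against 0.073 expected (Fisher's exact test, adjusted p = 0.000928 over 20 lists), a count chosen for mention after it was seen. All 3 carry the description Cyano fluorescent protein and can be pieces or alleles of one transcript, while the test counts them as independent, so its p is too small if they are. One Cyano fluorescent protein contig (contig152151) had no read in 2 corals (3 if crossed) and reached 177.6 in another, and Caspase-2 (contig175813) had none in 1 coral and reached 136.8. No contig of this kind was absent from all corals of one origin. Reads were counted on contigs, so an allele too different to align would also read as absent. That limit also covers Fibrillin-1 (contig218313), contig58852 and Rootletin (contig209488) of the origin comparison, which are among the 66.

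Other groupings were counted for each remaining comparison. For corals from pool 300 the real pattern gave 66 contigs and the highest of the other 3 gave 0, and for corals from pool 400 all 4 patterns gave 0. The 10 splits gave 0 contigs each for the difference between origins. For origin the real split gave 4 and the highest other 3, within pool 300 it gave 1, as did 4 of 10 splits with a highest of 2, and within pool 400 it gave 3 against 2. These splits are too few for a share under 0.05. With the crossed block, the sign pattern that gave 1557 contigs with rescaling and 1494 with edgeR had the deeper fragment of each of the 6 pairs on one side, so depth may move many contigs, which was seen after the fact and not tested further. As labelled, the pattern that gave 18 with rescaling had the deeper fragment on one side in 5 pairs. In the real pattern the pool 300 fragment was the deeper one in corals 2, 7, 40 and 68, so the pool comparison is itself partly aligned with depth. For lists, 7 of 32 patterns gave as many as the 3 called for pool, with a highest of 5, so chance is not excluded there, and 8 of 10 gave as many as the 1 called for origin, with a highest of 5.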
